A study of Mus musculus with 8 samples.

How the data were processed

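RNA of sorted mouse leukaemia cells was measured by RNA-seq in 8 libraries, 4 of cells given the empty vector (control) and 4 of cells given Cre (deleted). Per the labels' protocols, RNA was extracted with Trizol and libraries were made with the Illumina TruSeq RNA kit, and whether the libraries keep the strand is not given in the sources used here. Per the submitters' processing notes, the tools were Trim Galore, TopHat, HTSeq and edgeR 3.8.5 and the genome build was mm9, with no roles or order stated. No coordinates are given, since the reference annotation used here is of another build. Genes that overlap on either strand, or that have near-identical copies, cannot be fully separated in such counts.

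The deposited table holds 1 column per library and 23366 rows, with signal values that are gene read counts divided by the authors into a common scale, so they are not whole counts. Within each column, 100% of the values above 0 were whole multiples of a common step within a tolerance of 0.01 reads, so the whole read counts were recovered. The step that made this scaling is not named in the labels. The factors differ by at most 0.402% from median-of-ratios size factors computed from the recovered reads. A spreadsheet had turned 27 gene names into dates, and those rows entered the tests but are not named. A few other genes entered the tests and the counts and are not reported here by name. Of the 23366 names, 21780 matched a current mouse symbol, and older symbols in the gene lists were matched as well. No column belonged to an unmatched sample.

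The plan fixed before the data were examined was edgeR's quasi-likelihood test on counts. Because the deposited values are normalised, the main test became limma 3.58.1 on log2(value + 1), with a variance trend and robust empirical Bayes, on the 17847 genes with at least 10 normalised counts in at least 4 libraries. P-values were adjusted by Benjamini-Hochberg, with a threshold of 0.05. Fold changes are on the log2(value + 1) scale and understate changes of low genes. edgeR 4.0.16 and DESeq2 1.42.0 were run on the recovered reads as alternatives, in R 4.3.3, and figures were drawn with matplotlib 3.10.9. CPM values are recovered reads scaled to a library total of 1000000.

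The labels number both groups 1 to 4 and the design text names 4 mice, without saying that a number is a mouse. The pairing was therefore checked in the values. Deviations from the group means correlated between libraries of the same number at 0.502 to 0.663 over the tested genes, and between libraries of different numbers across the groups at 0.0403 at most. All 4 pairs lay above the bound of 0.1, which was set beforehand. The correlations and the calls of both fits were computed in the same step, so the choice was not made blind to the calls. On this basis the fit with the replicate number as a block is given beside the unpaired one. The fold changes of both fits are the same, since every pair has 1 library per group, and the SE and p-values differ. No 2 libraries of a group agreed within sampling noise, the lowest chi-square per degree of freedom being 50.1. There was no group with Cre and an intact Jmjd1c gene among the libraries analysed here.

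Gene lists were written from textbook knowledge before the data were examined, and 39 with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01, with p-values adjusted over the lists. Camera with an estimated correlation and fry, whose directional p asks whether a set's genes move one way on balance, were alternatives. Mitochondrially encoded genes were also listed, and none of the names was found in the table. Genes are named by a rule fixed beforehand. It takes Jmjd1c, then the 10 largest increases and 10 largest decreases among genes past the threshold whose groups do not overlap and whose mean is at least 5 CPM. From each list it adds up to 4 members past the threshold with the smallest p, or the most abundant member where none passed, and 2 members per marker list. The rule was fixed for the unpaired fit, and its use on the paired fit was added later. Some genes that the rule takes are not named below, among them most abundant members of lists that did not pass. List members named beyond the rule were chosen after their values were seen. They include Meis1, Kit, Myc, Mdm2, Kdm3a, Kdm3b, Vegfa, Aldoc and Smpdl3a, and members that make up counts of 5 or fewer. The filter and pseudocount were set once the unit was known, before any fit.

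The tests were run on simulated counts with the real genes' means, library sizes and pair effects, with 100 genes changed at each of 2 sizes among 17726. The changed genes were drawn from those with a mean of at least 1 CPM, so recovery of lower genes was not measured. Since the pair effects were built in, the simulation favours the paired fit. It holds no correlation between genes beyond these effects. For this comparison the unpaired fit recovered 60% of changes of 1 on the log2 scale and 5% of changes of 0.5, with 0 false calls. The paired fit recovered 97% and 67%, with 12 false calls among 176. Library depth of 53227579 to 80542514 reads sets the counting precision. The alternatives were other scalings, tools, filters and pseudocounts and each library or pair left out.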

Results

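RNA-seq was carried out on primary mouse leukaemia cells driven by MLL-AF9, a fusion oncogene that marks a subset of acute myeloid leukaemias. The cells carried GFP and a floxed Jmjd1c gene, which encodes a JmjC-domain protein of the KDM3 family of histone demethylases. Cells from 4 leukemic mice received a retrovirus with Cre recombinase and the Tomato reporter or a virus of the empty vector. Cells positive for both reporters were sorted 6 days after infection. There were 4 control libraries and 4 deleted libraries, with 62752581 ± 6385316 reads assigned to genes in the controls and 69214520 ± 11414622 in the deleted libraries (mean and SD). Totals ran from 53227579 reads in control replicate 1 to 80542514 in deleted replicate 4. A gene with 0 reads could be present at up to 0.0564 CPM in the shallowest library, a limit of 3 reads that covers counting error only.

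Jmjd1c itself, the targeted gene, was lower in all 4 deleted libraries than in any control. It had 19611 ± 2829 normalised counts in the control libraries and 10853 ± 378 in the deleted libraries (mean and SD, n = 4 each), a 1.79-fold decrease. The log2 fold change was -0.84 with an SE of 0.11 (limma, adjusted p = 0.0317) and an SE of 0.082 with the replicate number as a block (limma, adjusted p = 2.67e-04). The values count reads over the whole gene and the floxed exons were not separated, so the fall does not measure the share of cells with a deleted allele. Leaving out any 1 library except deleted replicate 2 took the unpaired limma test above the threshold of 0.05, to an adjusted p of up to 0.133. In the paired fit it stayed below 0.05 with any 1 of the 4 replicates left out.

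The comparison asked how loss of Jmjd1c changes the transcriptome of these leukaemia cells. All deleted libraries also had Cre, so exposure to Cre cannot be told apart from loss of Jmjd1c for any change below. Without pairing, 37 genes rose and 5 fell among 17847 tested (limma, adjusted p below 0.05), and in all 42 the 4 values of one group lay outside those of the other. Without 1 library these counts were 6 to 10 and 1 to 3, except without deleted replicate 2, when they were 211 and 47. Of all tested genes 5.94% were separated in this way. Chance would separate 2.86% if all 8 libraries were exchangeable. The pairing of the libraries goes against that, so 2.86% is not the chance share for these data. Libraries with the same replicate number deviated together, and with the replicate number as a block 1359 genes rose and 1172 fell, including all 42. The count test edgeR on recovered reads called 32 and 4 genes without the block and 1375 and 1195 with it. DESeq2 on the same reads called far more without the block, 397 and 168, and 1603 and 1292 with it. Of the limma calls with the block 53.7% were higher, against 41.6% with scaling to library size alone (1181 higher and 1660 lower). Without replicate 1 the paired fit called 529 and 236. Of the members of all lists, those that passed without pairing were Jmjd1c, Abcg1, Abca1, Cbs and Itgb3. In what follows, rose and fell refer to the paired fit unless the unpaired fit is named.

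Among genes of at least 5 CPM that passed without pairing, Itgb3 rose most. Itgb3, an integrin beta subunit, had 375 ± 41.2 normalised counts in the control libraries and 1631 ± 279 in the deleted libraries (mean and SD, n = 4 each), a 4.32-fold rise (log2 fold change 2.11, SE 0.14, limma adjusted p = 0.00186). Abcg1, a sterol exporter of macrophages, rose 4.27-fold (SE 0.21 on the log2 scale, limma adjusted p = 0.00917), and its partner Abca1 rose 2.32-fold (limma adjusted p = 0.0329). Ptplad2 rose 3.50-fold, Gas7 3.38-fold, Galnt9 3.12-fold and Thbd, which encodes thrombomodulin, 3.12-fold. The aryl hydrocarbon receptor gene Ahr and the endocytic adaptor gene Dab2 rose 2.81-fold and 2.81-fold. Tgfbr2, a TGF-beta receptor, rose 2.57-fold and the heparanase gene Hpse 2.55-fold. These 10 genes other than Abca1 had limma adjusted p values from 0.00186 to 0.0437 without pairing.

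Camk2b, which encodes the beta subunit of calcium/calmodulin-dependent kinase II, had the largest decrease. It fell 7.58-fold, from 61804 ± 21955 to 7837 ± 1337 normalised counts (SD, n = 4 each; log2 fold change -2.92, SE 0.26, limma adjusted p = 0.00495). The nucleoside transporter gene Slc28a2 fell 1.78-fold (limma adjusted p = 0.0480), and Cbs, which encodes cystathionine beta-synthase, fell 2.15-fold (limma adjusted p = 0.0329). The fifth gene that fell was Ascl2 (2.63-fold), singled out after its values were seen. The same rule for naming genes was also applied to the paired fit, which was decided on after the results of both fits had been seen. It added Htra3 (6.01-fold higher), Oit3 (5.52-fold), Gstt1 (5.39-fold), the C-type lectin gene Clec4n (5.13-fold), Wfdc17 (4.46-fold) and Tmcc3 (3.73-fold), with limma adjusted p values from 2.06e-06 to 4.00e-04 with the block. On the lower side it added Mpo, the myeloperoxidase gene of primary granules (6.71-fold lower, limma adjusted p = 0.0346), the granulocyte-monocyte progenitor gene Ms4a3 (1.97-fold), Celsr1 (2.02-fold), Ogdhl (2.0-fold), Cyp27a1 (1.96-fold) and Wdr34 (1.84-fold). Cbx6 and Npcd, which fell 2.21-fold and 1.96-fold, may share reads and are uncertain as separate genes.

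**Figure D1:**
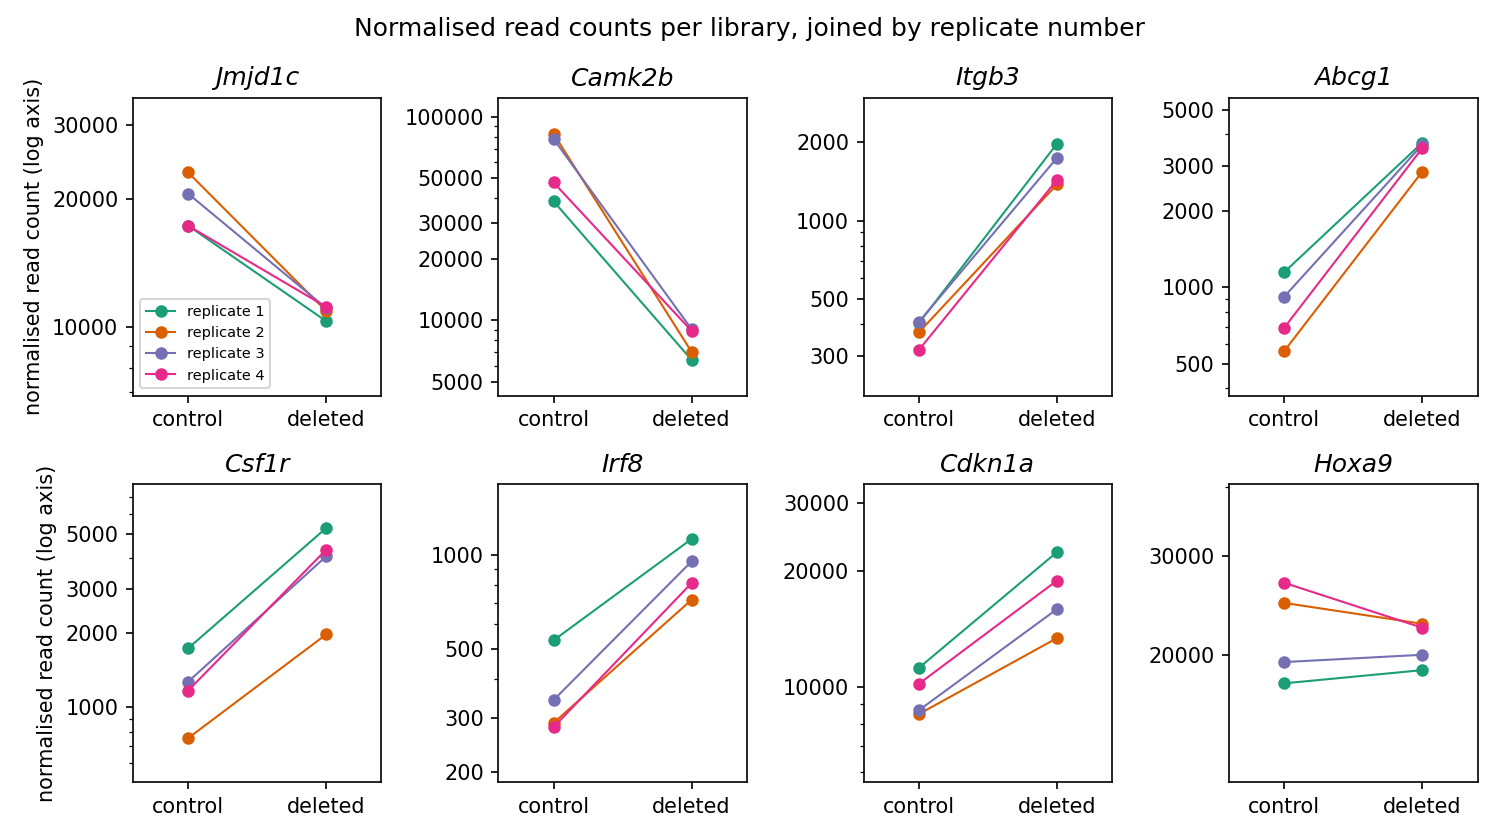
Normalised read counts of 8 genes in the 4 control and 4 deleted libraries (log axis), with points joined by replicate number. Jmjd1c and Camk2b lie lower and Itgb3, Abcg1, Csf1r, Irf8 and Cdkn1a higher in the deleted library of all 4 pairs, while Hoxa9 goes down in 2 pairs and up in 2.

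Counts for the HOXA genes that MLL fusions keep high stand beside 1359 rises and 1172 falls among all 17847 tested genes. Of 15 tested HOXA cluster and cofactor genes, 1 fell (1 also when adjusted over the list alone) and none rose. The list's pair medians were -0.09 ± 0.068, negative in 4 of 4 pairs, and 11 of its members were lower. Without replicate 4, 2 fell. The gene that fell was Hoxa11, 2.58-fold lower (limma adjusted p = 2.91e-04 with the block). Hoxa9 had a log2 fold change of -0.067 with a 95% confidence interval of -0.24 to 0.11, and its cofactor Meis1 one of 0.027 with an interval of -0.12 to 0.18 (paired limma fit, which bounds but does not exclude a change). Of 28 MLL fusion target genes 1 rose (Cpeb2) and 3 fell, and these were Jmjd1c itself, the RNA-binding protein gene Msi2 (1.35-fold lower) and Satb1 (1.49-fold lower). Without replicate 4, 5 MLL target genes fell. Among 29 leukaemia stem and progenitor cell genes 4 rose, Cd93 (1.97-fold), Cd34, Il2ra and the low-expressed Gfi1b (2.36-fold), and 3 fell, Msi2, Sox4 and Bmi1 (1 without replicate 1). This list's median was below 0 (-0.059) and its mean above (0.029). Kit had a log2 fold change of -0.089 (interval -0.28 to 0.10). Adjusted over the list alone, 1 and 3 MLL target genes and 4 and 6 stem and progenitor genes passed upwards and downwards. Camera, at its preset correlation, called none of these 3 lists (adjusted p = 0.0857, 0.236 and 0.740).

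By the share of members that rose, genes of monocytes and macrophages came first among the myeloid lists. Eosinophil markers had a larger median log2 fold change (0.86 against 0.71), and differences between lists were not tested. Of 38 tested monocyte and macrophage genes 24 rose, 0 fell and 14 did not pass, and the list's median log2 fold change was positive in 4 of 4 pairs (0.69 ± 0.19, mean and SD of the 4 pair medians). Csf1r, the receptor for macrophage colony-stimulating factor, rose 3.11-fold (log2 fold change 1.64, SE 0.084, limma adjusted p = 9.14e-06 with the block and 0.128 without). Mpeg1 rose 2.31-fold, the transcription factor gene Irf8 2.55-fold and the scavenger receptor gene Msr1 2.80-fold. Lyz2, the most abundant member, rose 2.27-fold (limma adjusted p = 0.00111), although reads of Lyz2 and its paralog Lyz1 may be shared. No member passed the unpaired test over all genes, and 18 passed it adjusted over the list alone. For this list camera adjusted p = 1.43e-17 at the preset correlation and adjusted p = 0.353 with an estimated correlation. Without replicate 1, 20 members rose. Of the 31 myeloid transcription factors 10 rose, among them Irf8, Egr1 (1.97-fold) and Nr4a1 (1.49-fold), and 2 fell, which were Gfi1 and Runx1 (1 without replicate 1, 3 or 4; camera adjusted p = 3.39e-05 at the preset correlation and adjusted p = 0.353 with an estimated correlation). This is not a separate set, as 5 of its members (3 of those that rose, with Irf8) are also in the monocyte list and 6 (4 that rose, with Egr1 and Nr4a1) in the immediate early list. It also shares 2 members with the primary granule list, of which 1 fell (Gfi1), and 4 with the IL3 and STAT5 target list, of which 3 rose.

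Single granulocyte genes moved in both directions. Of 14 genes listed for primary granules 4 fell, namely Mpo, Ms4a3, Gfi1 and Ctsg, the cathepsin G gene (2.01-fold lower), and 1 rose (Cst7, 2.34-fold). Gfi1 is a transcription factor gene and the same fall as in the transcription factor list. The primary granule list's pair medians were -0.28 ± 0.23, negative in 4 of 4 pairs, with camera adjusted p = 0.00585 at the preset correlation and adjusted p = 0.463 with an estimated correlation. Without replicate 1 or replicate 3, 1 primary granule gene fell in either case. Of 29 genes of later granules and mature neutrophils 2 rose, Hp (1.54-fold) and Il1b (4.41-fold), and 3 fell, Camp (1.62-fold), Ltf (3.92-fold) and Chi3l3. The pair medians of this list were -0.0088 ± 0.45, positive in 2 pairs and negative in 2, and S100a9, its most abundant member, had a log2 fold change of -0.046 (interval -0.55 to 0.45). Without replicate 4, 11 of its members fell, and 1 rose without replicate 2. With p adjusted over the list alone, 4 primary granule and 3 later granule genes fell and 1 and 2 rose, and 15 myeloid transcription factors rose and 2 fell.

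Target genes of p53, the DNA damage-responsive tumour suppressor, rose in part and none fell. Of 40 members 15 rose, with pair medians of 0.25 ± 0.038 that were positive in 4 of 4 pairs. The cell cycle inhibitor gene Cdkn1a rose 1.81-fold (log2 fold change 0.85, SE 0.072, limma adjusted p = 1.22e-04 with the block and 0.0960 without). Plk2 rose 2.50-fold, Zmat3 1.75-fold, Phlda3 2.02-fold and Mdm2, the p53 ubiquitin ligase gene, 1.4-fold. Rrm2b, the most abundant member, did not rise, with a log2 fold change of -0.085 (interval -0.27 to 0.10). For the list camera adjusted p = 2.29e-09 at the preset correlation and adjusted p = 0.353 with an estimated correlation, and 17 members passed adjusted over the list alone (13 without pairing). Without replicate 1 or replicate 4 the number that rose was 10 or 22. In the BCL2 family and cell death list 12 of 37 rose and 1, Bok, fell. Those that rose included pro-apoptotic Bmf (1.67-fold) and Pmaip1 (1.45-fold), the caspase genes Casp6 (1.58-fold) and Casp1 (1.41-fold), and also anti-apoptotic Mcl1 (1.27-fold) and the near-identical Bcl2a1 copies, which are uncertain one by one. It shares 6 members with the p53 list, of which 2 rose. This list had camera adjusted p = 3.50e-05 at the preset correlation and adjusted p = 0.353 with an estimated correlation, and 4 members rose without replicate 1 (14 rose and 1 fell when adjusted over the list alone).

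Many genes of DNA replication and of ribosome biogenesis fell. Of 50 cell cycle G1/S genes 25 fell and none rose, with pair medians of -0.30 ± 0.18. Dtl fell 1.46-fold, Ung 1.65-fold, Hells 1.35-fold and the helicase subunit gene Mcm2 1.42-fold (limma adjusted p from 0.00100 to 0.00365 with the block). G1/S genes had camera adjusted p = 3.43e-14 at the preset correlation and adjusted p = 0.410 with an estimated correlation. Among 48 MYC and nucleolar genes 19 fell and none rose (pair medians -0.22 ± 0.12), including Wdr12 (1.34-fold), Rrp9 (1.32-fold), Utp20 (1.31-fold) and Gnl3 (1.25-fold). They had camera adjusted p = 2.51e-11 at the preset correlation and adjusted p = 0.410 with an estimated correlation. Without replicate 1, 5 G1/S genes and 1 MYC and nucleolar gene passed, while the medians of both lists were negative in 4 of 4 pairs. Myc itself had a log2 fold change of -0.11 (interval -0.27 to 0.053). Of 74 cytosolic ribosomal protein genes 0 passed with the block in limma and 0 in edgeR, while 4 were lower and 0 higher at an unadjusted p below 0.05. Rplp0, the most abundant, had a log2 fold change of -0.08, and the list, whose pair medians were negative in 2 pairs, had camera adjusted p = 0.00364 at the preset correlation and adjusted p = 0.760 with an estimated correlation. Of 57 G2/M genes 9 rose, with Cdc25b 1.70-fold and Psrc1 1.68-fold higher, and none fell. Their pair medians were 0.25 ± 0.25, negative in replicate 4, without which 29 rose, and 4, 5 and 4 rose without replicates 1, 2 and 3. For G2/M genes camera adjusted p = 8.29e-10 at the preset correlation and adjusted p = 0.463 with an estimated correlation. Smc4, the most abundant G2/M gene, had a log2 fold change of 0.064 (interval -0.088 to 0.22). Adjusted over the list alone, 36 G1/S and 29 MYC and nucleolar genes fell and 16 G2/M genes rose with the block, and 0 of each without it.

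Part of the cytokine signalling and innate immune genes rose. Of 32 IL3 and STAT5 target genes 12 rose and none fell (pair medians 0.30 ± 0.14). They included the STAT5-induced inhibitor genes Cish (1.64-fold) and Socs1 (1.61-fold) and the IL3 receptor beta chain genes Csf2rb (1.68-fold) and Csf2rb2 (1.79-fold), close paralogs that may share reads. The cells were kept in 10 ng/ml IL3 in both groups. The IL3 list had camera adjusted p = 3.25e-08 at the preset correlation and adjusted p = 0.353 with an estimated correlation. Of its members that rose, 3 are also in the myeloid transcription factor list and 2 in the immediate early list. The NF-kB, cell death, and stem and progenitor cell lists each share 1 that rose with it. Of 55 interferon-stimulated genes 32 rose and none fell, among them Mx1 (3.67-fold), Zbp1 (2.03-fold), Parp14 (1.66-fold) and Xaf1 (2.19-fold). Pair medians were 0.39 ± 0.15, positive in 4 of 4 pairs, and 14 rose without replicate 1 and 21 without replicate 3. Interferon-stimulated genes had camera adjusted p = 2.47e-16 at the preset correlation and adjusted p = 0.402 with an estimated correlation. NF-kB and inflammatory genes rose in 13 of 31 cases, with the chemokine genes Ccl3 (2.17-fold), Ccl4 (1.96-fold) and Ccl2 (2.79-fold) and with Ier3 (1.68-fold), and had camera adjusted p = 4.43e-09 at the preset correlation and adjusted p = 0.410 with an estimated correlation. Of 29 immediate early and stress genes 10 rose, among them Klf2 (1.67-fold), Ier5 (1.71-fold) and Egr1, and 2 fell, Nr4a2 and Hsph1 (1 without replicate 1, 3 or 4; camera adjusted p = 4.62e-05 at the preset correlation and adjusted p = 0.353 with an estimated correlation). Hspa8, the most abundant member, did not pass, with a log2 fold change of -0.24 (interval -0.43 to -0.055). Antigen presentation genes rose in 8 of 23 cases, with Cd74, the invariant chain gene, 2.59-fold and H2-T23 1.29-fold higher (camera adjusted p = 9.51e-06 at the preset correlation and adjusted p = 0.421 with an estimated correlation), and in 2 without replicate 1 or 4 without replicate 3. Adjusted over the list alone, 16 IL3 and STAT5, 38 interferon-stimulated, 16 NF-kB, 15 immediate early and 10 antigen presentation genes rose with the block, and 3, 4, 0, 0 and 1 without it. Of these lists only the immediate early genes then had falls, 3 with the block.

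Other chromatin regulators are to be read beside all 17847 tested genes, of which 1359 rose and 1172 fell. Apart from Jmjd1c, 1 of the 25 histone demethylase genes rose (Jhdm1d, 1.29-fold) and Kdm2b fell 1.22-fold. In the demethylase list 0 rose and 1 fell without replicate 1, and 3 fell without replicate 4. The nearest relatives of Jmjd1c had log2 fold changes of 0.17 for Kdm3a (interval 0.011 to 0.34) and -0.023 for Kdm3b (interval -0.16 to 0.11). Of 36 histone methyltransferase and MLL complex genes 3 fell, Smyd2 (1.38-fold), Ezh2 (1.21-fold) and Prmt1 (1.21-fold), and none rose (1 fell without replicate 1 and 1 without replicate 2). The pair medians of this list were -0.09 ± 0.052, negative in 4 of 4 pairs, and 7 of its members fell with scaling to library size alone. Camera gave the demethylase list an adjusted p of 0.968, its median changing sign with scaling to library size alone, and for the methyltransferase list camera adjusted p = 0.0295 at the preset correlation and adjusted p = 0.463 with an estimated correlation. When adjusted over the list alone, 1 demethylase gene rose and 2 fell, and 2 methyltransferase genes fell.

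Markers of other blood and stromal cells were measured beside these groups. Of megakaryocyte and platelet markers 6 of 14 rose, including Itgb3 and Gp1bb (1.33-fold), while Nfe2, the most abundant, had a log2 fold change of 0.11 (camera adjusted p = 3.66e-04 at the preset correlation and adjusted p = 0.410 with an estimated correlation). Eosinophil markers rose in 3 of 8 cases (Siglec5, 1.94-fold, and the paralogs Ear2 and Ear6, which may share reads; camera adjusted p = 0.00511 at the preset correlation and adjusted p = 0.353 with an estimated correlation), dendritic cell markers in 3 of 10 (Itgax, H2-Aa and H2-Ab1, while the most abundant, Bst2 and Tcf4, had log2 fold changes of 0.065 and 0.24; camera adjusted p = 0.00836 at the preset correlation and adjusted p = 0.410 with an estimated correlation), and stromal markers in 4 of 12 (Fn1 1.34-fold, Acta2 1.52-fold, Cxcl12 and Lepr; camera adjusted p = 0.00803 at the preset correlation and adjusted p = 0.353 with an estimated correlation). Itgax is also in the monocyte list, and H2-Aa and H2-Ab1 in the antigen presentation list. Without replicate 1, 1 dendritic cell marker rose. Of 13 B cell markers 3 fell (Blnk, 1.41-fold, Cd79b and Vpreb3; Fcrla had a log2 fold change of 0.20) and none rose, and of 9 T cell markers 1 fell (Lck, 1.35-fold; Thy1, -0.067). Of 7 mast cell and basophil markers 1 fell (Ms4a2; Cpa3 and Hdc, the most abundant, did not pass, at -0.29 and -0.48). Erythroid markers gave 1 rise and 1 fall among 12 (Car2 and Klf1; Tfrc -0.19, Car1 0.094), and endothelial markers 2 and 1 among 9 (Pecam1 1.36-fold higher and Vwf, against Eng; Tek 0.032). Camera called none of these last 5 lists (lowest adjusted p = 0.153). Adjusted over the list alone, 7 megakaryocyte, 5 eosinophil, 6 dendritic cell and 4 stromal markers rose and 4 B cell and 1 dendritic cell markers fell, while 2 mast cell markers rose and 3 fell, and 2 endothelial markers rose and 2 fell. Without replicate 1 the falls of B and T cell markers numbered 1 and 0, the erythroid rises 0 and the endothelial rises and falls 1 and 0. Without replicate 2, 2 mast cell markers rose and 2 fell, 2 T cell markers fell and 1 B cell marker rose. Without replicate 3, 0 erythroid markers rose and 2 mast cell markers fell, and without replicate 4 these were 2 and 2, with 1 B cell marker that fell. The 4 tested natural killer cell markers were too few for a list test, and 0 passed in limma or edgeR and 0 at an unadjusted p below 0.05 (Klrb1c 0.29, Klrd1 0.41).

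**Figure D2:**
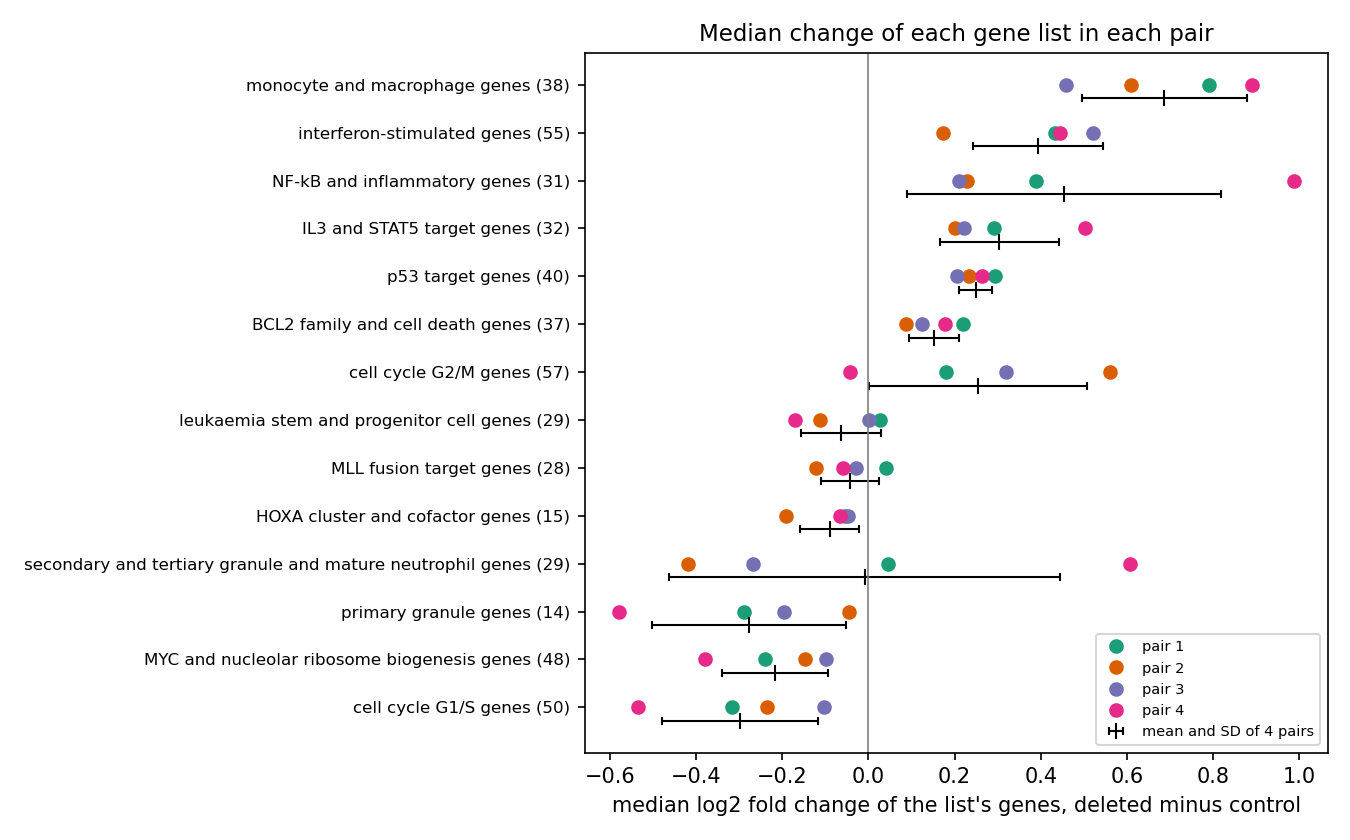
Median log2 fold change (deleted minus control) of the tested genes of 14 lists in each of the 4 pairs, with the number of genes in brackets; black bars give the mean and SD of the 4 pair medians. The monocyte and macrophage list lies highest, at 0.69 ± 0.19, and the G1/S list lowest, at -0.30 ± 0.18.

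In the paired fit camera at its preset correlation called 19 lists higher and 6 lower of the 39 tested, and none with an estimated correlation.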

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

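No test of an explanation is reported in this part. In 38 of 412 comparisons of the 4 libraries of a group (9.22%), 1 library lay apart, where chance gives about 1 in 20 for a single comparison. The comparisons reuse the same libraries, on selected genes that vary together and on means of lists that hold some of them. The share is therefore not a test of an excess. The number given for each is its gap to the nearest other library as a share of the range of the 4, compared with the 95% critical value of Dixon's test, with its side of the other 3.

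Control replicate 2 stood apart in 10 comparisons: H2-D1 (0.833, below), Bmf (0.907, below), Dtl (0.839, above), Utp20 (0.837, above), Slc16a1 (0.943, above), Idh3a (0.853, above), Mvd (0.937, below), Ezh2 (0.883, above), the mean of the cell cycle G1/S genes list (0.944, above) and the mean of the cholesterol efflux and LXR target genes list (0.915, below). Deleted replicate 2 did so in 11: Tgfbr2 (0.969, below), Atp5b (0.871, above), Wdr34 (0.860, above), Hp (0.925, below), Egr1 (0.941, below), Wdr12 (0.892, above), Gnl3 (0.832, above), Slc16a1 (0.836, above), Wipi1 (0.951, below), the mean of the MYC and nucleolar ribosome biogenesis genes list (0.884, above) and the mean of the cholesterol efflux and LXR target genes list (0.907, below). Slc16a1 and the cholesterol efflux genes set replicate 2 apart on the same side in both groups.

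For deleted replicate 1 there were 8: Hist1h1c (0.945, above), Csf2rb (0.833, above), Gfi1b (0.895, above), Casp6 (0.903, above), Hist1h2bc (0.954, above), Acsl3 (0.880, below), Ctss (0.909, above) and the mean of the hypoxia and HIF target genes list (0.850, above). For control replicate 4 there were 3: Camp (0.837, below), the mean of the antigen presentation genes list (0.953, above) and the mean of the B cell marker list (0.853, above). Deleted replicate 4 gave 3 as well: Camp (0.841, below), Ltf (0.917, below) and the mean of the replication-dependent histone genes list (0.951, below). Camp was lower in replicate 4 than in the other 3 libraries of both groups. In control replicate 3 there were 2, Cbx6 (0.849, above) and Npcd (0.843, above) genes that are uncertain as separate ones. The last was the read total (0.879, below) in control replicate 1, the shallowest library.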

How the results depend on the processing

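The alternatives of the paired fit, edgeR on recovered reads, TMM scaling and the other pseudocounts were chosen after the data had been seen. Without pairing, the 37 higher and 5 lower genes became 397 and 168 with DESeq2, 21 and 2 with at least 5 CPM in at least 4 libraries (fewer genes tested) and 1359 and 1172 with the replicate block. Scaling to library size alone gave 8 lower. Without 1 library they ranged from 6 to 211 and from 1 to 47. In the paired fit, leaving out 1 replicate gave 529 to 1589 higher and 236 to 1303 lower. Jmjd1c kept its direction, with log2 fold changes of -0.90 to -0.76 without 1 library, but in the unpaired fit passed only without deleted replicate 2 (limma adjusted p = 0.0228; 0.0543 to 0.133 otherwise). In the paired fit it passed whichever replicate was left out (adjusted p = 4.15e-05 to 0.00499).

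Of the lists called by camera at the preset correlation, 0 higher and 0 lower were called with an estimated correlation, with or without pairing. Over all 39 lists tested, fry called 0 higher and 0 lower without pairing and 12 and 1 with the replicate block. The lower one was the B cell marker list (fry adjusted p = 0.0304), which camera had not called. Lists that camera called lower, such as G1/S (fry adjusted p = 0.0814), did not pass in fry. The 12 hold the unfolded protein response list (fry adjusted p = 0.0493), which camera had not called either. The replication-dependent histone list changed direction with the 5 CPM filter (camera adjusted p = 0.637 unpaired and 0.538 paired). The cause was not tested for these changes. Over all comparisons of list tests in the paired fit, 440 were unchanged in call, 46 lost and 12 gained a call. In the unpaired fit these were 605, 76 and 12. Both tallies include the estimated correlation and fry, and direction was compared only for lists called in the starting fit. Named genes were unchanged in call, lost and gained one in 2085, 60 and 9 cases with pairing and in 2867, 80 and 209 without. Their direction was compared only where a gene was called in either fit of the comparison. At 53227579 to 80542514 reads, depth limits genes near the floor of 0.0564 CPM. With libraries thinned to the smallest total, the paired fit called 1365 higher and 1114 lower genes, against 1359 and 1172. Whether the genes that changed call lie near the floor was not tested.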

Other observations

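Tests of other cell types' markers, of C1q and Apoe, of the splits of the libraries and of the Camk2b neighbourhood were chosen after the results had been seen, while the GC, depth and Cre questions were written down before their results. Genes of sterol handling and of the lysosome rose in part with the replicate block. Among cholesterol efflux and LXR target genes 6 of 13 rose and 0 fell, with Abcg1, Abca1, Mylip (1.67-fold) and Smpdl3a (1.42-fold) among them (camera adjusted p = 1.88e-04 at the preset correlation and adjusted p = 0.353 with an estimated correlation). Of the cholesterol synthesis genes 7 of 24 rose and 0 fell, with Mvd 1.33-fold higher (camera adjusted p = 7.34e-04 at the preset correlation and adjusted p = 0.547 with an estimated correlation), and 3, 4 and 4 rose without replicates 1, 2 and 3. Of the autophagy and lysosome genes 14 of 38 rose and 1 fell, with Ctsb 1.60-fold and Wipi1 1.46-fold higher (camera adjusted p = 1.07e-05 at the preset correlation and adjusted p = 0.410 with an estimated correlation; 4 rose without replicate 1), and 2 of those that rose, with Ctsb, are also in the monocyte list. Adjusted over the list alone, 7 cholesterol efflux, 8 cholesterol synthesis and 17 lysosome genes rose and 1, 2 and 1 fell.

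Of the hypoxia and HIF target genes 8 of 24 rose and 0 fell, with Slc2a1 1.33-fold and Vegfa 1.22-fold higher (camera adjusted p = 3.14e-04 at the preset correlation and adjusted p = 0.410 with an estimated correlation; 2 without replicate 1), and 2 of those that rose are also in the glycolysis list. Of the glycolysis genes 6 of 28 rose and 1 fell, with Aldoc 1.27-fold higher and the lactate transporter gene Slc16a1 1.52-fold lower (camera adjusted p = 0.0142 at the preset correlation and adjusted p = 0.618 with an estimated correlation), and 0 and 2 rose without replicates 1 and 3. Of tricarboxylic acid cycle and nuclear-encoded oxidative phosphorylation genes 0 of 76 rose and 4 fell, namely Idh2, Idh3a, Suclg2 and Fh1 (camera adjusted p = 0.0585; 1 fell without replicate 1 or 3, and 3 rose without replicate 4). Of the fatty acid genes 3 of 34 rose and 3 fell (camera adjusted p = 0.606), but 0 fell without replicate 1 and 5 rose without replicate 2. Of the ATF4 and amino acid response genes 3 of 36 rose and 4 fell (camera adjusted p = 0.236), against 1 and 2 without replicate 1. In the unfolded protein response list 1 of 23 rose and 0 fell (Edem1; camera adjusted p = 0.0535), 0 rose without replicate 1, and 3 rose and 1 fell without replicate 4. Of the replication-dependent histone genes 3 of 56 rose and 18 fell, with Hist1h1c higher, but near-identical copies make single members uncertain and 0, 9 and 11 fell without replicates 1, 3 and 4, with 1 rising without replicate 1 (camera adjusted p = 0.00813 at the preset correlation and adjusted p = 0.737 with an estimated correlation). The 56 genes together had a mean of only 204 CPM in the control libraries and 196 CPM in the deleted libraries. When adjusted over the list alone, 10 hypoxia and 8 glycolysis genes rose and 0 and 1 fell, 4 fatty acid and 3 histone genes rose and 5 and 21 fell, and 1 tricarboxylic acid cycle gene fell.

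Cyp2r1, a vitamin D 25-hydroxylase gene singled out after its values were seen, had 174 reads in the 4 deleted libraries (32 to 54 each) and 6 in the 4 controls (1 to 3 each). Scaled for the read totals of the groups, the ratio was 26.3 with a 95% counting interval of 11.8 to 72.6. This interval treats reads as independent and leaves out variation between libraries. Camk2b fell without its neighbours doing so alike: the 10 nearest tested genes had a median log2 change of -0.15 (-1.29 to 0.12), and 2 of them fell with the block, Aebp1 and Pold2. A loss over the whole neighbourhood is thus unlikely to account for the fall of Camk2b.

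The higher monocyte and macrophage genes could reflect other cells in the sort or a change in the leukaemia cells. Markers of T, B, natural killer, erythroid and mast cells had a median log2 change of -0.075, below that of the monocyte list by 0.76 ± 0.19 (SD over 4 pairs). Eosinophil, dendritic cell, megakaryocyte and stromal markers had pair medians of 0.66 ± 0.30, 0.33 ± 0.30, 0.43 ± 0.29 and 0.22 ± 0.10. So far as these markers measure other cells, this argues against a rise of every other type alike but not against cells of some types. Which cells in the sort express the markers is not known. Tfrc had a mean of 145 CPM, while the 4 tested natural killer markers together had 1.43 CPM in the controls. C1qb, a complement gene of macrophages, rose 3.29-fold with the block, the C1q genes together gained 1.23 ± 0.688 CPM against 39.3 ± 14.1 CPM for Csf1r, and with Apoe, which made up 97.4% of the control sum, the change was -1.06 CPM, so this sum leaves macrophages open. With the trend with GC and length removed the list's median was 0.71, and with libraries thinned to the smallest total it was 0.72, against 0.71 before either change. Monocytes or macrophages in the sort, which took cells positive for both reporters, and a shift of the leukaemia cells towards monocytes as a hypothesis, stay open. Such a shift could follow from Cre itself as well as from loss of Jmjd1c.

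The rise of p53 target genes may follow from loss of Jmjd1c or from Cre itself. With GC and length trends removed the median log2 fold change of the list's members was 0.23, against 0.18 before, which argues against that bias as the whole cause. Exposure to Cre cannot be told apart from loss of Jmjd1c, since 0 libraries analysed here had Cre and an intact gene. The same holds for the other genes and lists that changed.

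The replicate numbers pair the libraries, so the real split compares with the 8 splits of the 8 libraries that part all 4 pairs, too few for a share under 0.05. Among these the real split gave 42 genes without pairing against 0 at the highest other, and 2531 with pairing against 0. In the other splits the real contrast of the exchanged pairs adds to the variance, which lowers their gene counts. These counts therefore do not show what chance alone gives. For lists it gave 25 against 21 without pairing and 25 against 22 with it. Both of these highest others came from the split that exchanges replicate 2 alone and keeps the real contrast in the other pairs. The splits with as many control as deleted libraries on each side called 5, 5 and 12 lists without pairing. With pairing they called 6, 12 and 11, so a list count above 0 also arises without the real contrast. In each case 1 split, the real one, gave as many. Of all 35 splits into 4 and 4, most of which part fewer pairs, the highest other gave 17 genes, in a split that keeps the numbers together, and 24 lists.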
